A study of Homo sapiens with 18 samples.

How the data were processed

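RNA was measured by stranded mRNA sequencing in 18 libraries of hTERT RPE-1, a line of human retinal pigment epithelial cells immortalised with telomerase reverse transcriptase. Per the labels' protocols, cells kept in 10% serum were starved for 48 h in 0.1% serum, exposed for 30 min to 50 µM etoposide, a poison that traps topoisomerase II on cleaved DNA, and then given 10 µM triptolide, which blocks transcription through the XPB subunit of TFIIH. The sample titles name the arm without etoposide DMSO. The labels give the samples the time points 0, 20 and 40. They state neither the unit nor whether triptolide had been added at 0, so the numbers are used here as names of the time points. Each of the 6 groups holds 3 samples that the labels call independent replicates and number 1 to 3. RNA was purified on RNeasy columns, treated with the TURBO DNA-free kit and made into libraries with the TruSeq Stranded mRNA kit, per the labels' protocols.

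The deposited files hold raw counts of reads per gene, as whole numbers without normalization. Per the submitters' processing notes, the authors used bcl2fastq, HISAT2 and featureCounts with the human build GRCh38 (also named hg38). The versions, the annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. Each file lists the same 58051 Ensembl gene identifiers. Of these, 57447 matched GENCODE release 29 on GRCh38, from which positions and gene types were taken, and 41944 received a symbol. The 37 genes of the mitochondrial chromosome had 0 counts in all libraries together. Total counts ranged from 7957691 to 11580219 per library, so that 3 counts, the floor of a gene's detection, corresponded to 0.259 to 0.377 CPM (counts scaled to a common library total of 1e6). Shares of counts are given with exact Clopper-Pearson 95% intervals, which cover counting error only.

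Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (robust, R 4.3.3) in one model of the 6 groups over all libraries, with TMM factors (0.978 to 1.02) and edgeR's default filter, which kept 14186 genes holding 99.84% of the counts. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p below 0.05. All adjusted p of single genes come from this test unless another tool is named. The comparisons were etoposide against DMSO at each time point, the change from 0 to 20 and from 0 to 40 in each arm, and the interaction, which is the change with etoposide minus the change with DMSO. Standard errors (SE) of log2 changes were derived from the F statistic. Normalised values are given as mean CPM ± SD of 3 libraries.

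Sets of genes were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 between genes, adjusted over the lists with at least 5 tested members. The 21 lists were fixed in advance and cover early-response, p53 target, NF-kB target, heat shock, integrated stress response, m6A machinery, topoisomerase and adduct repair, mRNA decay, transcription machinery and proliferation genes. They also cover AU-rich element genes, small RNA host genes, nuclear noncoding RNAs, stable housekeeping mRNAs, mitochondrially encoded mRNAs, cytosolic ribosomal protein genes, ZNF genes, and genes of retinal pigment epithelium, of fibroblasts, of other epithelia and of blood. Of 162 list tests, 35 passed the threshold. With a correlation estimated per list, 6 of these passed, namely the early-response, AU-rich element and ZNF lists in the change from 0 to 40 of both arms. With the replicate block and an estimated correlation 9 passed, these 6 and, from 0 to 40, the NF-kB target list in both arms and the integrated stress response list with DMSO. Genes were named by a rule that took, for each comparison but those of time point 20, the 8 largest called changes in each direction with a mean CPM of 5 or more and replicate values that did not overlap, and up to 4 members of each list with the smallest p. The rule added 8 check genes (TOP2A, TOP2B, METTL3, METTL14, FOS, JUN, MYC and CDKN1A) in every comparison and allowed the text to name fewer genes than it gives.

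Same-numbered libraries deviated together from their group means. All 45 pairs of libraries with the same number had positive correlations over genes, from 0.359 to 0.911, against a minimum of 0.1 set for treating the numbers as pairs. Libraries of numbers 1 and 2 also correlated with each other, from 0.392 to 0.63, and both correlated negatively with number 3, which the first principal component (67.8% of the variance) separated from the rest. Part of the positive values of numbers 1 and 2 therefore comes from replicate 3 standing apart. Each of the 18 libraries had its highest correlation with a library of its own number. By the minimum set, the numbers from the labels were taken to pair the samples, before the calls of the fits were compared. The fit without a block had been planned and stayed the main one, although it leaves the replicate effect in each gene's spread. The common coefficient of variation between replicates was 0.316 in it and 0.119 with the replicate number as a block. The fit with the block is given beside a result where it changed the call or moved a count of called genes by more than 1.5 times. Counts at an unadjusted p are given without the block, and were higher with it in every comparison. Replicate libraries of a group differed by more than sampling noise, with chi-square per degree of freedom of 9.08 to 56.6, so none was counted as a duplicate. Residual degrees of freedom were 12, and 10 with the block.

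The list step was tested on simulated counts in which 1 list of 30 genes was moved by 0.5 on the log2 scale and 20 lists were not. Without the replicate block the moved list passed (camera adjusted p = 3.94e-40) and 0 of the 20 others did. Genes were drawn independently there, so this could not test the preset correlation between genes. The edgeR step was tested on other simulated counts, with 200 changed genes. For 3 against 3 libraries with a replicate effect as in these data (etoposide against DMSO at time point 40, 13995 genes), 40% of genes changed by 1 on the log2 scale and 78% of those changed by 2 were called, and with the block 77% and 97%. For the interaction from 0 to 40 these shares were 16% and 69%, and with the block 58% and 94%. The comparisons, tests, gene lists, naming rule and a first set of alternatives were chosen before the data were examined. The alternatives covered scaling, filters, DESeq2 1.42.0, limma-voom, the replicate block, fits of the compared groups alone, a minimum change, time as a number, and leaving out each library. Further ones were added after the data were seen, and the closing section gives the effect of all.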

Results

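The series followed how RNA levels fell once transcription was blocked in serum-starved hTERT RPE-1 cells, with and without etoposide beforehand, to compare RNA stability between the 2 arms. Each arm was sampled at time points 0, 20 and 40 of triptolide, a unit of time not being stated in the labels, with 3 replicates per group and 18 libraries in all. Total counts per library ranged from 7957691 to 11580219 (median 10114787.5), and 17854 to 20410 genes had a count. RNA was scaled to each library's own total, so a change is relative to the other RNAs of the library and not to the number of cells.

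Some libraries stood apart on features other than their group. The 3 replicates of a group were not alike, since all libraries of replicate 3 had 0 counts of 44 protein-coding genes that averaged over 5 CPM in replicates 1 and 2. Examples were the small RNA host SNHG32 at 122 CPM in replicates 1 and 2, the receptor kinase gene DDR1 at 106 CPM, the proteasome subunit gene PSMB3 at 78.5 CPM and the cytokine gene MIF at 44.9 CPM, all chosen after their values were seen. Of the 44 genes, 15 lay among the 59 expressed genes of the MHC region and 7 among the 8 of the pseudoautosomal region. Genes typed as antisense held 1.42% of the counts (exact 95% interval 1.413% to 1.429%) in the second DMSO library of time point 0 and 0.217% to 0.253% in the other libraries. BEST1, a chloride channel gene of retinal pigment epithelium, had 21473 counts there and at most 177 in any other library. TUBA1B-AS1 and VIM-AS1, named after their values were seen, also stood highest there, at 6348 and 8436 counts against at most 31 and 292 elsewhere. The count of BEST1 in that library is therefore not read as expression of BEST1. The second etoposide library of time point 20 also stood apart. It had the fewest genes with a count, 17854, and the lowest value on the third principal component (−35.1, 4.08% of the variance). Its correlations with the other libraries of number 2 were 0.359 to 0.559.

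In the DMSO arm, RNAs of early-response genes and of genes with AU-rich elements, among others, had fallen by time point 40 of triptolide. ADM, which encodes the vasodilator peptide adrenomedullin, fell from 136 ± 16.3 to 20.0 ± 0.862 CPM (SD, n = 3 each), and SOCS3, a feedback inhibitor of cytokine signalling, fell from 24.4 ± 4.9 to 2.73 ± 0.646 CPM. MYC, a growth-promoting transcription factor, fell from 59.9 ± 8.45 to 14.8 ± 4.05 CPM. Genes of the early response to growth factors and stress fell together, with a median log2 change of −1.10 and negative values in 45 of 46 tested members (camera adjusted p = 2.87e-56). ADM lies on chromosome 11 at 10304680 to 10307397 (ENSG00000148926), SOCS3 on chromosome 17 at 78356778 to 78360077 (ENSG00000184557) and MYC on chromosome 8 at 127735434 to 127741434, in GRCh38.

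Of 14186 genes tested with edgeR and Benjamini-Hochberg adjustment, 60 were lower at 40 than at 0 in the DMSO arm and 0 were higher (576 genes at an unadjusted p under 0.05). The log2 change was −2.76 for ADM (SE 0.16, adjusted p = 1.45e-07), −3.15 for SOCS3 (SE 0.22, adjusted p = 9.06e-07) and −2.01 for MYC (SE 0.26, adjusted p = 0.000696). Early-response genes held 14 of the called genes (27 adjusted over the list alone). With the replicate block they held 32 over all genes and 36 over the list alone, and below such pairs of counts stand in this order. The members called without the block included ZFP36 and ZFP36L1, which encode proteins that bind AU-rich elements and promote mRNA decay, at −3.16 (SE 0.6) and −1.83 (SE 0.16), and the kinase-like gene TRIB1 at −2.63 (SE 0.31). They also included IER2 at −2.24 (SE 0.27), the transcriptional repressor gene SNAI1 at −2.17 (SE 0.42), ID1 at −2.0 (SE 0.21) and the kinase gene SGK1 at −1.66 (SE 0.2). FOS, at −2.59 (SE 0.87), and JUN, at −1.60 (SE 0.44), did not pass (adjusted p = 0.577 and 0.274) and did with the replicate block (adjusted p = 0.00165 and 1.01e-07).

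Genes with AU-rich elements in their transcripts fell as a list in the DMSO arm (median log2 change −0.26, 30 of 36 negative, camera adjusted p = 9.63e-17). Called members numbered 5 (10 adjusted over the list alone, 11 and 18 with the replicate block). Among them were ARRDC3 at −1.97 (SE 0.19), the kinase gene PIM1 at −0.96 (SE 0.15) and the transcription factor gene SOX9 at −0.91 (SE 0.14). ZNF genes, which mostly encode zinc finger proteins, had a median of −0.15, with 293 of 408 negative (camera adjusted p = 6.27e-10) and 2 called (6 adjusted over the list alone, 14 and 22 with the replicate block). The called genes were ZNF574 and ZNF526, both at −1.06 (SE 0.15 and 0.2). Small RNA host genes had a median of −0.16 with 3 of 22 called (4 adjusted over the list alone), namely SNHG3 at −0.92 (SE 0.14), SNHG15 at −1.07 (SE 0.21) and SNHG12 at −1.39 (SE 0.27). That list's camera adjusted p was 1.7e-08, with adjusted p = 0.166 with an estimated correlation. Within replicates 1, 2 and 3 its median was 0.0174, −0.285 and −0.445, so the list did not fall in replicate 1. Its member SNHG32 had 0 counts in replicate 3. MIR23AHG, a microRNA host, fell by 2.27 (SE 0.41).

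NF-kB target genes had a median log2 change of −0.73 in the DMSO arm, with 20 of 22 negative and 0 called (3 adjusted over the list alone, 8 and 11 with the replicate block). The camera adjusted p of that list was 1.3e-06, with adjusted p = 0.564 with an estimated correlation and 0.0135 with that and the replicate block. NFKBIA, the inhibitor of NF-kB, stood at −2.11 (SE 0.46, adjusted p = 0.0757, and 4.35e-08 with the replicate block). Integrated stress response genes had a median of −0.21 with 0 of 17 called (3 adjusted over the list alone, 4 and 5 with the replicate block). Its camera adjusted p was 0.000894, with adjusted p = 0.564 with an estimated correlation and 0.0126 with that and the replicate block. DDIT4 stood at −2.68 (SE 0.8, adjusted p = 0.383, and 5.36e-09 with the replicate block). Of p53 target genes 1 of 33 was called (3 adjusted over the list alone, 3 and 5 with the replicate block), PLK2 at −1.75 (SE 0.32). The list had a median of −0.092, a camera adjusted p of 0.00302 and an adjusted p = 0.121 with an estimated correlation. CDKN1A, the cell cycle inhibitor p21, stood at −0.43 (SE 0.21, adjusted p = 1).

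The replicate block raised the DMSO count to 173 genes, 171 of them lower, and these held all 60. limma-voom called 48 and DESeq2 115. Without DMSO replicate 1 or 2 of time point 0 the count was 34 or 35, without DMSO replicate 1 or 2 of time point 40 it was 27 or 31, and a fit of the compared groups alone gave 12. EIF4A1, a translation initiation factor gene, at −3.16 (SE 0.32), and the ribosomal protein gene RPL36A, at −1.95 (SE 0.39), are uncertain because other annotated genes overlap them.

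In the etoposide arm, RNAs of early-response genes and of genes with AU-rich elements were also lower at time point 40 than at 0. ADM fell from 116 ± 13.0 to 28.4 ± 3.74 CPM (SD, n = 3 each), SOCS3 from 25.8 ± 3.78 to 5.58 ± 0.867 CPM and MYC from 45.6 ± 11.8 to 16.8 ± 3.22 CPM. Early-response genes had a median log2 change of −0.77, with 40 of 46 negative.

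With edgeR and Benjamini-Hochberg adjustment, 29 of 14186 genes were lower at 40 than at 0 in the etoposide arm and 0 were higher (431 genes at an unadjusted p under 0.05). The log2 change was −2.03 for ADM (SE 0.16, adjusted p = 9.5e-06), −2.21 for SOCS3 (SE 0.21, adjusted p = 4.97e-05) and −1.44 for MYC (SE 0.25, adjusted p = 0.0215). Early-response genes held 8 of the called genes (17 adjusted over the list alone, 23 and 31 with the replicate block; camera adjusted p = 4.04e-31). They included TRIB1 at −2.18 (SE 0.3), DUSP6, a phosphatase acting on ERK, at −1.60 (SE 0.29), IER2 at −1.46 (SE 0.27), ZFP36L1 at −1.39 (SE 0.15), ID1 at −1.36 (SE 0.21) and KLF6 at −1.12 (SE 0.17). FOS stood at −2.18 (SE 0.85, adjusted p = 1) and JUN at −0.95 (SE 0.43, adjusted p = 1), and both passed with the replicate block (adjusted p = 0.00849 and 0.000141).

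AU-rich element genes fell as a list in the etoposide arm (median −0.28, 31 of 36 negative, camera adjusted p = 7.77e-17) with 3 called (10 adjusted over the list alone, 8 and 15 with the replicate block). They included ARRDC3 at −2.04 (SE 0.19) and SOX9 at −0.77 (SE 0.14). ZNF genes had a median of −0.21 with 329 of 408 negative (camera adjusted p = 4.8e-17) and 1 called (1 adjusted over the list alone, 9 and 26 with the replicate block), ZNF574 at −0.91 (SE 0.15). Small RNA host genes had a median of −0.21 with 1 of 22 called (5 adjusted over the list alone, 5 and 8 with the replicate block), SNHG3 at −1.20 (SE 0.14). That list had a camera adjusted p of 3.69e-09 and an adjusted p = 0.14 with an estimated correlation. NF-kB target genes had a median of −0.58 with 0 of 22 called (0 adjusted over the list alone, 5 and 12 with the replicate block). Their camera adjusted p was 3.2e-05, with adjusted p = 0.63 with an estimated correlation and 0.0243 with that and the replicate block. NFKBIA stood at −1.45 (SE 0.45, adjusted p = 0.616, and 1.18e-05 with the replicate block), and the p53 target PLK2 at −1.57 (SE 0.32, adjusted p = 0.069, and 1.45e-08 with the replicate block). The microRNA host MIR222HG fell by 1.98 (SE 0.26). EIF4A1, uncertain for the overlap named above, stood at −3.67 (SE 0.33).

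Genes of the m6A machinery, which writes, removes or reads N6-methyladenosine on mRNA, had a median of −0.090 in the etoposide arm, with 20 of 22 negative and 0 called (0 adjusted over the list alone, 0 and 2 with the replicate block). The camera adjusted p was 0.0058, and adjusted p = 0.14 with an estimated correlation. Within replicates 1, 2 and 3 the list's median was −0.0478, 0.0701 and −0.0347 with DMSO, and −0.0404, −0.16 and −0.0308 in the interaction. Neither passed, and the list passed only in the etoposide arm from 0 to 40. RBM15, a subunit of the methyltransferase complex, stood at −0.67 (SE 0.19, adjusted p = 0.426). Integrated stress response genes had a median of −0.11 (0 of 17 called, 0 adjusted over the list alone, 3 and 3 with the replicate block) and a camera adjusted p of 0.0533, which was 0.00374 with the replicate block (adjusted p = 0.137 with the block and an estimated correlation). DDIT4 of that list stood at −2.67 (SE 0.79, adjusted p = 0.557, and 1.29e-08 with the replicate block). Stable housekeeping mRNAs were relatively higher (median 0.10, 26 of 26 positive, camera adjusted p = 0.0032, adjusted p = 0.69 with an estimated correlation). So were ribosomal protein genes (median 0.073, 74 of 79 positive, camera adjusted p = 0.0139, adjusted p = 0.908) and proliferation genes (median 0.065, 23 of 30 positive, camera adjusted p = 0.0325, adjusted p = 0.337). Without the replicate block none of these 3 lists had a called member (0 adjusted over the list alone). With the block RPL36A of the ribosomal list, uncertain for overlapping genes, was called as lower, at −1.29 (SE 0.28, adjusted p = 0.0175, against −1.34, SE 0.38 and adjusted p = 0.402 without it). The medians of the 3 lists became −0.00094, −0.031 and −0.037 when libraries were scaled to housekeeping and ribosomal protein genes, which moved the median of all genes by −0.1. The first 2 lists are the genes scaled to, so that their medians near 0 follow from the scaling itself. The p53 target list had a median of 0.0025, 0 called members (1 adjusted over the list alone, 1 and 1 with the replicate block) and a camera adjusted p of 0.924. Its median was −0.0286 when scaled by library size and −0.102 under the housekeeping scaling.

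The replicate block raised the etoposide count to 143 genes, which held all 29, limma-voom called 30 and DESeq2 66. The count was 13 without etoposide replicate 1 of time point 0, 12, 12 and 17 without etoposide replicate 1, 2 or 3 of time point 40, and 6 in a fit of the compared groups alone.

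Most of the genes called with etoposide were also called with DMSO. Of the 60 called with DMSO and the 29 called with etoposide, 27 were the same genes, where 0.123 would be met by independent lists. Fisher's exact test across genes (two-sided) gave p = 3.15e-65, which treats genes as independent and does not measure replication between samples. The arms share no libraries, but both calls come from the same fit, which shares each gene's estimate of spread. All 62 genes called in either arm had a negative change in both, and 53 of them changed less with etoposide, although 60 of the 62 had been selected for their fall with DMSO, which favours larger values there. With the replicate block 102 genes were called in both arms, and of the 212 called in either, 208 had a negative change in both and 143 changed less with etoposide. The difference between arms was tested gene by gene as the interaction, given with the etoposide effect.

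**Figure D1:**
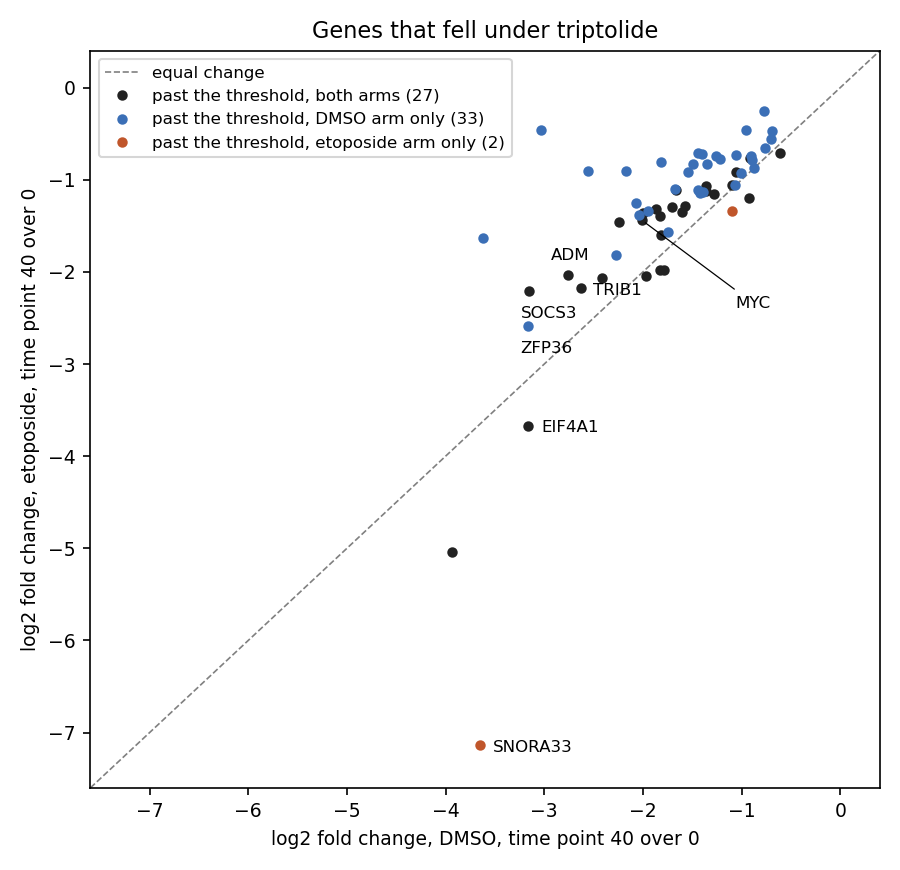
Log2 fold change from time point 0 to 40 with DMSO (horizontal) and with etoposide (vertical) for the 62 genes called in at least 1 arm, 3 libraries per group, with a dashed line of equal change. Most points (53 of 62) lie above the line, where the fall with etoposide was smaller, and SNORA33, labelled after its value was seen, stands lowest at −3.65 and −7.14.

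**Figure D2:**
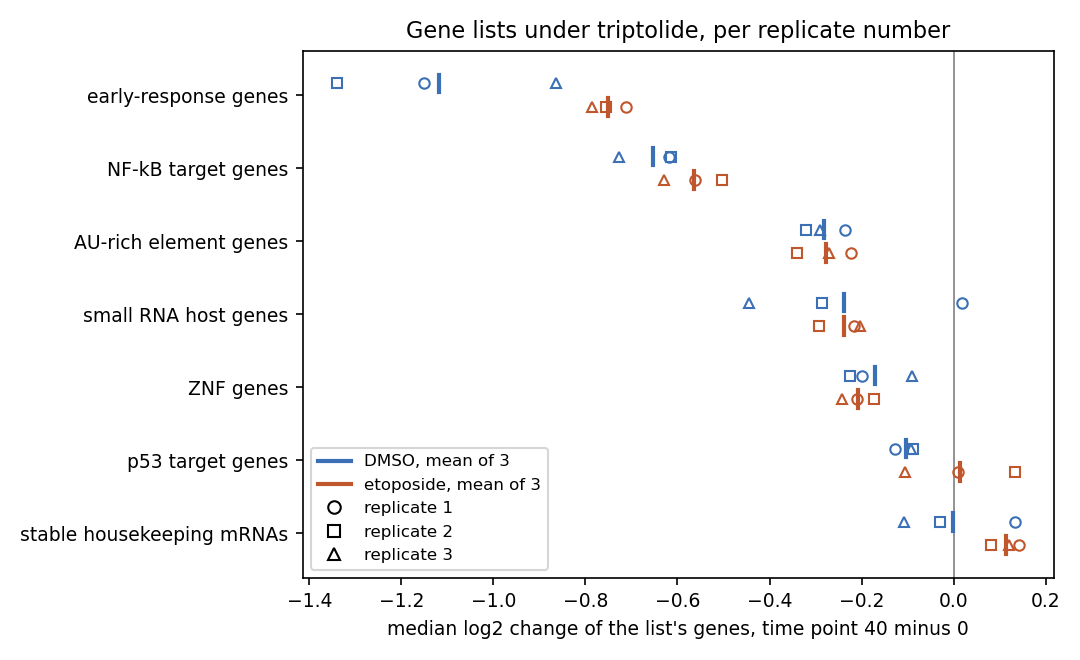
Median log2 change of each gene list from time point 0 to 40, taken within each replicate number (open symbols) with the mean of 3 (bars), for DMSO and etoposide. Early-response genes stood at −1.15, −1.34 and −0.863 with DMSO and at −0.711, −0.755 and −0.785 with etoposide.

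After etoposide, early-response RNAs stood higher at time point 40 than with DMSO, with a median log2 difference of 0.29 and positive values in 40 of 46 members. The list's camera adjusted p was 4.36e-09, with adjusted p = 0.287 with an estimated correlation. BTG2, an antiproliferative p53 target that is also an early-response gene, was at 5.37 ± 2.82 CPM with etoposide and at 0.498 ± 0.35 CPM with DMSO (SD, n = 3 each), the latter near the floor of 3 counts (0.259 to 0.377 CPM). It lies on chromosome 1 at 203305491 to 203309602 in GRCh38 (ENSG00000159388). None of the genes named next passed edgeR's test, with or without the replicate block. The log2 difference was 1.40 (SE 0.42) for SNAI1, 1.03 (SE 0.21) for SOCS3, 0.77 (SE 0.23) for the kinase gene PLK3, 0.56 (SE 0.15) for PIM1 and 0.49 (SE 0.14) for IER5.

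At time point 40 edgeR called 0 genes between etoposide and DMSO (139 at an unadjusted p under 0.05, fewer than by chance). With limma-voom 0 genes were called and with DESeq2 1, BTG2. The log2 difference of BTG2 was 3.39 (SE 0.57, edgeR adjusted p = 0.324), and with the replicate block 3.37 (SE 0.45, adjusted p = 0.0029), where it was the 1 gene called. The call with the block was lost without DMSO replicate 1 of time point 40 (adjusted p = 0.118) and in limma-voom with the block (adjusted p = 0.093). Without the block, edgeR called BTG2 when etoposide replicate 3 of time point 40 was left out (adjusted p = 0.0461) and when replicate 3 was left out of all groups (log2 difference 3.65, adjusted p = 0.0126). The early-response list had 0 called members (1 adjusted over the list alone, 1 and 7 with the replicate block). p53 target genes had a median of 0.067 with 23 of 33 positive (0 called, 0 adjusted over the list alone, 0 and 7 with the replicate block), a camera adjusted p of 0.016 and an adjusted p = 0.287 with an estimated correlation. Within replicates 1, 2 and 3 their median was 0.128, 0.204 and −0.0515. In that list the apoptosis gene BBC3 stood at 0.96 (SE 0.37), GADD45A, a DNA damage response gene, at 0.35 (SE 0.14) and CDKN1A at 0.37 (SE 0.21), each with an adjusted p of 1. Proliferation genes were relatively lower (median −0.0785, 22 of 30 negative, 0 called, 0 adjusted over the list alone, camera adjusted p = 0.031, adjusted p = 0.417 with an estimated correlation). NF-kB target genes (median 0.18, 0 called, 0 adjusted over the list alone, 0 and 2 with the replicate block) and integrated stress response genes (median 0.082, 0 called, 0 adjusted over the list alone) did not pass (camera adjusted p = 0.233 and 0.338) and did with the replicate block (adjusted p = 0.0031 and 0.0186), a call lost with the block and an estimated correlation (adjusted p = 0.602 and 0.42). MYC stood at 0.18 (SE 0.25, adjusted p = 1).

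**Figure D3:**
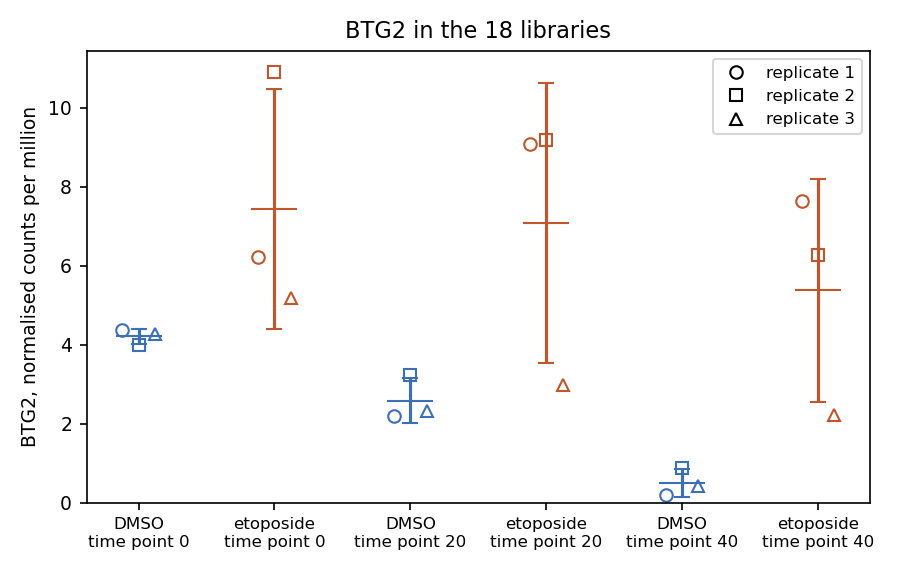
BTG2 in normalised CPM in each of the 18 libraries by arm and time point, with the mean and SD of 3 libraries. At time point 40 the DMSO libraries lie between 0.192 and 0.88 and the etoposide libraries between 2.22 and 7.64.

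The interaction asks whether the change from 0 to 40 differed between the arms. Early-response genes fell less with etoposide, by a median of 0.40 on the log2 scale with 41 of 46 positive (camera adjusted p = 4.7e-09, adjusted p = 0.3 with an estimated correlation). The values were 2.56 (SE 0.74) for BTG2, 1.27 (SE 0.57) for SNAI1, 0.64 (SE 0.29) for ID1, 0.52 (SE 0.19) for IER5, 0.65 (SE 0.61) for JUN and 0.57 (SE 0.35) for MYC, and 0.94 (SE 0.29) for SOCS3 outside the list. p53 target genes had a median of 0.099 with 22 of 33 positive (camera adjusted p = 0.0177, adjusted p = 0.3 with an estimated correlation), and of 0.106, 0.34 and −0.0459 within replicates 1, 2 and 3. Members included PLK3 at 0.70 (SE 0.33), AEN, an apoptosis nuclease, at 0.58 (SE 0.26), GADD45A at 0.51 (SE 0.2) and CDKN1A at 0.46 (SE 0.3). Nuclear noncoding RNAs changed in the opposite direction (median −0.31, 9 of 9 negative, camera adjusted p = 0.0279, adjusted p = 0.643 with an estimated correlation). Between the arms their median within replicates 1, 2 and 3 was 0.244, 0.165 and 0.087 at time point 0. At 40 it was 0.394, −0.19 and −0.0459. They thus stood higher with etoposide at 0 in each replicate, while the arms differed in no common direction at 40. These 3 lists had 0 called members (0 adjusted over the list alone). Adjusted over the list alone, 12 early-response and 2 p53 target genes passed with the replicate block. edgeR called 0 genes with or without the replicate block (190 at an unadjusted p under 0.05 without it), and limma-voom and DESeq2 called 0, so each single-gene value above has an adjusted p of 1.

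At time point 0, proliferation genes stood slightly lower with etoposide than with DMSO, relative to the other genes. Proliferation genes had a median log2 difference of −0.16 with 28 of 30 negative (camera adjusted p = 0.000266, adjusted p = 0.169 with an estimated correlation). Members included TYMS, which makes thymidylate, at −0.22 (SE 0.1), E2F1 at −0.24 (SE 0.13) and the replication clamp gene PCNA at −0.20 (SE 0.12). Ribosomal protein genes had a median of −0.11 with 78 of 79 negative (camera adjusted p = 0.000476, adjusted p = 0.874), with RPL39L at −0.45 (SE 0.21). Nuclear noncoding RNAs were relatively higher (median 0.12, 9 of 9 positive, camera adjusted p = 0.00361, adjusted p = 0.735 with an estimated correlation), with MEG3 at 0.55 (SE 0.21) and NEAT1, the scaffold of paraspeckles, at 0.39 (SE 0.19).

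Stable housekeeping mRNAs were lower in the same comparison (median −0.10, 25 of 26 negative, camera adjusted p = 0.0123, adjusted p = 0.829 with an estimated correlation). Scaling to housekeeping and ribosomal protein genes moved the median of all genes by 0.11, which took the proliferation median to −0.049 and, by its construction, the medians of the ribosomal and housekeeping lists to −0.0044 and 0.0094. The early-response list had a median of −0.080 and a camera adjusted p of 0.0889 (0.00792 with the replicate block, and adjusted p = 0.702 with the block and an estimated correlation). Its median was 0.033 under that scaling. These 5 lists had 0 called members (0 adjusted over the list alone, where 2 nuclear noncoding RNAs passed with the replicate block). edgeR called 0 genes (378 at an unadjusted p under 0.05), as did limma-voom and DESeq2. BTG2 stood at 0.82 (SE 0.49), MYC at −0.39 (SE 0.25) and BEST1 at −6.98 (SE 1.8), each with an adjusted p of 1. The value of BEST1 rests on the second DMSO library of time point 0, in which antisense-type genes held 1.42% of counts, and is not read as a change in BEST1 expression.

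By time point 20 the shifts were small and seen in gene groups, with no single gene past the threshold. FOS stood at −0.87 (SE 0.81) with DMSO and −0.85 (SE 0.81) with etoposide, both with an adjusted p of 1. Early-response genes fell as a list with DMSO (median −0.23, 35 of 46 negative, camera adjusted p = 1.01e-05, adjusted p = 0.5 with an estimated correlation), as did AU-rich element genes (median −0.098, 27 of 36 negative, camera adjusted p = 0.0332, adjusted p = 0.317). With etoposide the early-response list did not pass (median −0.118, 31 of 46 negative, camera adjusted p = 0.0708). It did with the replicate block (adjusted p = 0.0216), though not with the block and an estimated correlation (adjusted p = 0.556). Its interaction from 0 to 20, which tests the difference between the arms, did not pass (median 0.102, camera adjusted p = 0.194). With etoposide, ZNF genes were lower (median −0.0775, 272 of 408 negative, camera adjusted p = 0.00073, adjusted p = 0.168 with an estimated correlation), and proliferation genes were relatively higher (median 0.11, 29 of 30 positive, camera adjusted p = 0.000401, adjusted p = 0.168). Within replicates 1, 2 and 3 these medians were −0.104, 0.0152 and −0.164 for ZNF genes. For proliferation genes they were 0.0291, 0.282 and 0.0416, so that rise came mostly from replicate 2.

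Also with etoposide at 20, ribosomal protein genes (median 0.098, 76 of 79 positive, camera adjusted p = 0.00073, adjusted p = 0.744 with an estimated correlation) and housekeeping mRNAs (median 0.076, 23 of 26 positive, camera adjusted p = 0.0395, adjusted p = 0.744) were relatively higher, with medians of 0.026 and, turned in sign, −0.0031 under the scaling to these same genes. Nuclear noncoding RNAs were lower (median −0.13, 7 of 9 negative, camera adjusted p = 0.0395, adjusted p = 0.744). The interaction from 0 to 20 was positive for proliferation genes (median 0.18, 26 of 30 positive, camera adjusted p = 0.000127, adjusted p = 0.137 with an estimated correlation) and negative for nuclear noncoding RNAs (median −0.16, 7 of 9 negative, camera adjusted p = 0.0124, adjusted p = 0.611). Within replicates 1, 2 and 3 the median was 0.0857, 0.267 and 0.173 for proliferation genes. For nuclear noncoding RNAs it was −0.885, 0.0317 and 0.00282, negative in replicate 1 only. The lists named for time point 20 had 0 called members (0 adjusted over the list alone). Adjusted over the list alone, 4 early-response genes and 1 AU-rich element gene passed with DMSO and the replicate block. edgeR, limma-voom and DESeq2 each called 0 genes in the changes from 0 to 20 of DMSO and etoposide, in the interaction and between arms at 20 (199, 142, 139 and 108 at an unadjusted p under 0.05 with edgeR).

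TOP2A and TOP2B, the targets of etoposide, and METTL3 and METTL14, the core of the m6A methyltransferase, were not called in any comparison, with a largest absolute log2 difference of 0.305 (SE 0.24, edgeR adjusted p = 1). The topoisomerase and adduct repair list had its smallest camera adjusted p at 0.247. Heat shock genes reached 0.0889, mRNA decay genes 0.355, transcription machinery genes 0.471, retinal pigment epithelium genes 0.398 and fibroblast genes 0.394, none past the threshold in any comparison. Of other epithelial genes 2 and of blood cell genes and mitochondrially encoded mRNAs 0 were tested, so these 3 lists had no list test.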

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

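All tests in this part, the splits of the samples included, were chosen after the results were seen, except the interaction tests of the lists. The change with etoposide differed from that with DMSO in 5 list tests of the interaction. From 0 to 20 these were proliferation genes (median 0.18, camera adjusted p = 0.000127) and nuclear noncoding RNAs (median −0.16, camera adjusted p = 0.0124). From 0 to 40 they were early-response genes (median 0.40, camera adjusted p = 4.7e-09), p53 target genes (median 0.099, camera adjusted p = 0.0177) and nuclear noncoding RNAs (median −0.31, camera adjusted p = 0.0279). With an estimated correlation none of the 5 passed (adjusted p = 0.137, 0.611, 0.3, 0.3 and 0.643), nor with the replicate block as well (0.607, 0.628, 0.148, 0.369 and 0.369). The median kept its sign in replicates 1, 2 and 3 for proliferation genes, early-response genes and, from 0 to 40, nuclear noncoding RNAs. It was −0.885, 0.0317 and 0.00282 for nuclear noncoding RNAs from 0 to 20, and 0.106, 0.34 and −0.0459 for p53 target genes.

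The smaller fall of early-response RNAs with etoposide had medians of 0.662, 0.290 and 0.150 within the 3 replicate numbers. The list's difference between arms was −0.322, 0.0847 and −0.0271 at time point 0, and 0.384, 0.418 and 0.0739 at 40. In replicates 1 and 3 part of the value thus comes from a lower start with etoposide. At the preset correlation the smaller fall did not rest on the doubted second DMSO library of time point 0 alone. Without that library and with the replicate block the camera adjusted p was 2.03e-17. With an estimated correlation the list did not pass even with all libraries, with or without the block. A slower loss of short-lived RNAs in general was looked for in the AU-rich element genes. They had a median interaction of 0.0183, where 0.0786 was predicted from their own fall. Within replicates 1, 2 and 3 the median was −0.00257, 0.0373 and 0.00313 (SD 0.022), below the prediction each time. The test cannot decide whether these genes slowed by the same share, by less or not at all. The error of the prediction was not estimated, and members spread by 0.323 (SD). The prediction was also a single pooled value, while the early-response fall it drew on varied between replicates. That fall had medians of −1.15, −1.34 and −0.863 with DMSO and −0.711, −0.755 and −0.785 with etoposide. Whether the early-response RNAs decayed more slowly or were still made under triptolide stays open, because no nascent RNA or spike-in was measured. An effect of etoposide on them remains a hypothesis, because the list did not pass with an estimated correlation and no single gene was called in the interaction.

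The libraries of replicate 3 stood apart on the first principal component (67.8% of the variance). Lower depth is argued against, because the least expressed of the 44 genes without a count should have had 300 counts over the 6 libraries. Reads aligned or counted against another reference or annotation are a candidate explanation, since 30 of the 44 genes had a neighbour also without a count, where the highest of 1000 shuffles gave 4, and 271 of the 294 genes 4-fold or more higher in replicate 3 were pseudogenes, against 741 of 14186 tested. A difference between cultures cannot be told apart from it, because without the 606 genes 4-fold apart the first component held 33.2% of the variance and still separated replicate 3. No biological explanation from the design was tested, since each replicate number holds all 6 groups.

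In the second DMSO library of time point 0, 543 genes were 8-fold or more above every other library, where any other library had at most 1 such gene. Of these genes 93.2% lay opposite an exon of an expressed gene, which is consistent with a partial loss of strand information in that library. Genomic DNA as the whole cause is argued against, since it should raise genes without regard to strand partners and 6.95% of all genes lie opposite such an exon, although silent genes summed to 127 CPM against 60.1 to 79.1 CPM in other libraries, a measure revised after a first version was seen to favour the genes it was picked on. Antisense transcription of the DMSO group is argued against, because antisense-type genes held 0.247% and 0.217% of the counts of its other libraries. Both lie below the highest library of the other groups (0.253%) and far below this one (1.42%).

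For the splits of the samples, 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split gave 60 genes in the DMSO arm and 29 in the etoposide arm from 0 to 40 (1 of 10 splits each), and the highest of the others gave 0. With the replicate block, among the 4 splits that part all 3 pairs, the real one gave 173 and 143 and the highest other 1 and 0, and between the arms at 40 it gave 1 against 0. For etoposide against DMSO at each time point and for both changes from 0 to 20, the real count was 0 and the highest other 0. That all 10 of 10 splits gave as many follows from the 0 and says nothing about chance. For the interactions the real count was likewise 0, so that all 100 of 100 drawn splits gave as many by construction. The highest other split called 0 genes from 0 to 20 and 135 from 0 to 40, the latter a sign of structure among the samples whose nature was not tested.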

How the results depend on the processing

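The alternatives with replicates 1 and 2, without the second DMSO_T0 library, without genes 4-fold apart in replicate 3, without a whole replicate, with the block in DESeq2, limma-voom or each left-out library, and with the block and an estimated correlation, were chosen after the results were seen. Scaling to mitochondrial mRNAs was not run because these had 0 counts. The cause was not tested for any change below, except that fewer groups or libraries leave fewer degrees of freedom. Depth of 7957691 to 11580219 counts limits genes near 0.259 to 0.377 CPM.

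For the change from 0 to 40, the DMSO count (60), etoposide count (29) and shared count (27) became 173, 143 and 102 with the replicate block, 115, 66 and 53 with DESeq2, 12, 6 and 4 in fits of the compared groups alone, 171, 136 and 96 with limma-voom and the block, and 241, 151 and 109 with DESeq2 and the block. With the block they were 132, 148 and 94 without the second DMSO_T0 library, 98, 56 and 54 with replicates 1 and 2, and 174, 154 and 106 without the genes 4-fold apart, and the etoposide count was 49 with replicates 1 and 2 without that library. With libraries or replicates left out, with or without the block, the DMSO and etoposide counts ranged from 2 to 221 and from 0 to 194. The shared count, for which these were run without the block, ranged from 0 to 35. Without replicate 1, 2 or 3 as a whole they were 2, 8 and 78, 0, 5 and 36, and 0, 4 and 35. The highest counts with libraries left out, 221 and 194, came with the block without the second etoposide library of time point 20. That library is in neither comparison.

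Between arms at 40 the count (0) was 1 with the block, 1 with DESeq2, 2 with the block without the second DMSO_T0 library (BTG2 and ZBTB39), 1 with replicates 1 and 2, 1 with these without that library, 3 with DESeq2 and the block (BTG2, PLK3 and ZBTB39), and 5 with the block without genes 4-fold apart (BTG2, SNAI1, PLK3, RGS2 and ZBTB39). It was 0 with limma-voom and the block (BTG2 adjusted p = 0.093) and 0 with the block without DMSO_T40 replicate 1 (BTG2 adjusted p = 0.118). Genes outside the naming rule were chosen after their values were seen. With libraries left out it ranged from 0 to 3. At 0 the count (0) was 17 with DESeq2 and the block, and 0 to 3 with libraries left out. For DMSO from 0 to 20 the count (0) was 1 with the block without the second DMSO_T0 library (EIF3CL), 11 with DESeq2 and the block, and 0 to 5 with libraries left out, and the interaction from 0 to 40 ranged from 0 to 1. BTG2 at 40 ranged from 2.68 to 4.10, with adjusted p from 1.38e-05 to 1.

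With an estimated correlation, list adjusted p were 0.564 (NF-kB), 0.166 (small RNA hosts), 0.121 (p53) and 0.564 (integrated stress response) for DMSO from 0 to 40, and 0.63 (NF-kB), 0.14 (small RNA hosts), 0.14 (m6A), 0.337 (proliferation), 0.69 (housekeeping) and 0.908 (ribosomal) for etoposide. They were 0.287 (early-response), 0.287 (p53) and 0.417 (proliferation) between arms at 40, 0.3, 0.3 and 0.643 (early-response, p53, nuclear) for the interaction from 0 to 40, and 0.169, 0.874, 0.735 and 0.829 (proliferation, ribosomal, nuclear, housekeeping) between arms at 0. For time point 20 they were 0.5 and 0.317 (early-response, AU-rich, DMSO), 0.168, 0.168, 0.744, 0.744 and 0.744 (proliferation, ZNF, ribosomal, housekeeping, nuclear, etoposide) and 0.137 and 0.611 (proliferation, nuclear, interaction). With the block and an estimated correlation, 9 of 162 list tests passed, namely the 6 without the block and 3 more, at 0.0135 (NF-kB, DMSO to 40), 0.0126 (integrated stress response, DMSO to 40) and 0.0243 (NF-kB, etoposide to 40). The others stayed lost, at 0.0676 (small RNA hosts) and 0.173 (p53) for DMSO to 40, 0.0687, 0.297, 0.434, 0.434 and 0.708 (small RNA hosts, m6A, proliferation, housekeeping, ribosomal) for etoposide to 40, 0.174, 0.42 and 0.602 (early-response, p53, proliferation) between arms at 40, 0.148, 0.369 and 0.369 (early-response, p53, nuclear) for the interaction to 40, and 0.443, 0.727, 0.443 and 0.702 (proliferation, ribosomal, nuclear, housekeeping) between arms at 0. For time point 20 they were 0.307 and 0.307 (early-response, AU-rich, DMSO), 0.556 for each of proliferation, ZNF, ribosomal, housekeeping and nuclear (etoposide), and 0.607 and 0.628 (proliferation, nuclear, interaction).

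Scaling to housekeeping and ribosomal genes gave 0.0241 (integrated stress response), 0.257 (proliferation) and 0.0749 (ribosomal) for etoposide from 0 to 40, 0.0418 (NF-kB, arms at 40), 0.248 (nuclear, interaction to 40), 0.0788 and 0.0788 (nuclear, housekeeping, arms at 0), 0.0854 (AU-rich, DMSO to 20), 0.0828 and 0.155 (housekeeping, nuclear, etoposide to 20) and 0.0688 (nuclear, interaction to 20). For the housekeeping and ribosomal lists these values follow in part from scaling to the same genes. The scaling moved the median of all genes by 0.11 between arms at 0, −0.1 for etoposide from 0 to 40 and −0.11 for its interaction. Median-ratio factors gave 0.0484 (integrated stress response, etoposide to 40), and library size alone 0.051 (proliferation, etoposide to 40), 0.0502 and 0.0502 (housekeeping, nuclear, etoposide to 20).

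With the replicate block, the 3 fits without the second DMSO_T0 library, with replicates 1 and 2, and with both limits follow each value of the block. These were 0.00374, then 0.00696, 0.0307 and, not past the threshold, 0.0698 (integrated stress response, etoposide to 40), 0.0031, then 0.00515, 0.0197 and 0.0258 (NF-kB, arms at 40), 0.0186, then 0.0273 and, not past the threshold, 0.0552 and 0.0922 (integrated stress response, arms at 40) and 0.00792, then 0.00121, 0.00794 and 1.1e-06 (early-response, arms at 0), and 0.0216, then 0.0252, 0.00298 and 0.00581 (early-response, etoposide to 20). The early-response interaction to 20 was 0.052 with the block and passed in those 3 fits (0.0257, 0.0141 and 9.36e-05), all at the preset correlation. With the block and an estimated correlation this interaction did not pass. Calls lost with replicates 1 and 2, and then also without that library, were 0.253 and 0.266 (proliferation, etoposide to 40), 0.173 and 0.202 (nuclear, interaction to 40), 0.0751 and 0.161 (housekeeping, arms at 0), 0.225 and 0.286 (ZNF, etoposide to 20), 0.172 and 0.272 (housekeeping, etoposide to 20), and 0.0796 in the latter (ribosomal, arms at 0). Of 162 list tests the block added 12 calls to the 35 and ended 0, and 7 of the 12 are not in the report, namely NF-kB (etoposide to 20), nuclear (etoposide to 40), p53 and ribosomal (interaction to 20) and integrated stress response, housekeeping and ribosomal (interaction to 40). With the block and an estimated correlation 0 of the 12 passed (adjusted p from 0.137 to 0.793; of the 5 in the report 0.137, 0.602, 0.42, 0.702 and 0.556, in the order above). Beyond the calls named here and in the report, the block changed no other call of a gene or list given in the report.

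Of 3008 alternative values of 81 gene values in the report, 2704 kept direction and side of the threshold, 197 lost and 107 gained the call, and 0 reversed. That 0 reversed follows in part from which values were given, since check-gene values that changed sign are outside the 81. The 8 check genes have 72 values, of which 41 changed sign in at least 1 alternative, none of them the 2 called (MYC in both arms to 40), with the largest such value 0.403. It was decided after these values were seen to give 57 of the 72 as a summary, and all 41 that changed sign are among them. Of their 2680 alternative values 142 changed sign. The largest absolute difference of TOP2A, TOP2B, METTL3 and METTL14, taken anew over genes and comparisons in each alternative, ranged from 0.282 to 0.43. The value given above, 0.305 for METTL14 in the interaction from 0 to 20, itself ranged from 0.101 to 0.43.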
